A study of Homo sapiens with 3 samples.

How the data were processed

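RNA sequencing was used to compare 3 PC3-Luc lines, each represented by 3 libraries. PC3 is an androgen-independent prostate adenocarcinoma line derived from a bone metastasis, and PC3-Luc carries a luciferase gene brought in with an MSCV vector, per the labels. The control hairpin line was set against 2 lines with short hairpins against CTHRC1, named sh718 and sh720 in the labels. Per the labels' protocols, the cells grew for 24 h in 6-well plates, RNA was taken with spin columns and DNase I, and single reads of 75 bp were made on a NovaSeq6000, with 3000000 reads stated per sample.

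The authors deposited a table of raw counts per Ensembl gene, with no normalization, for 9 libraries. GEO lists 1 sample per line, and the table holds 3 numbered columns for each of them. Each column was taken as a library of the line it is named for. Nothing in the sources used here says whether the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Per the submitters' processing notes, Trim Galore and the genome build GRCh38 were used. The aligner, the counting program, the strand setting and the annotation release are not given in the sources used here. Genes that overlap, antisense genes and genes with near-identical copies are therefore uncertain, since their reads may have been split or placed on one copy. The table lists 21726 genes, all with at least 1 count over the 9 libraries. Library totals ran from 883663 to 1108960 counts.

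Gene symbols, classes and chromosomes are those of the deposited table. Positions came from the GENCODE v29 annotation of GRCh38, in which 21258 of the listed identifiers were found. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit and glmQLFTest) on all 9 libraries in 1 model of the 3 lines, with Benjamini-Hochberg adjustment per comparison. A gene was called at an adjusted p under 0.05, and every adjusted p printed for a gene comes from this test unless DESeq2 is named. The test covered 9556 genes whose counts, summed per line, averaged at least 20 over the 3 lines. The comparisons were sh718 against control, sh720 against control, and sh718 against sh720, the last being the test of a difference between the hairpins. All changes are log2 values with their standard error (SE). Levels are TMM-scaled CPM, computed here, as mean ± SD over 3 libraries. The common biological coefficient of variation was 5.89%. The median change of all tested genes lay within 0.00237 of 0 on the log2 scale in every comparison.

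The comparisons, their tests, the rule for the genes named and 28 gene lists were fixed before the data were examined. That plan used a rule of size without a test for 1 library per line, and edgeR on all lines if the table turned out to hold replicate libraries, which it did. The genes named were CTHRC1, and the 12 highest and 12 lowest genes called in the same direction with both hairpins, ranked by the bound of the 95% interval nearest to no change, the weaker hairpin deciding. They also included at most 5 genes called in opposite directions and the 5 highest and 5 lowest genes in sh718 against sh720, by the same rank. Of each list, at most 4 members per direction called with both hairpins were named, or otherwise at most 2 members with the highest counts. The members of a list described beyond these, and genes said to be so, were picked after their values were seen. For a gene at 0 counts in all libraries of a line, the fold is a lower bound set by 3 counts over that line. With 1 to 3 counts in a line, the ratio of summed counts is given with its exact 95% counting interval.

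The lists were mesenchymal markers, epithelial junction and keratin genes, collagens and matrix proteins, matrix proteases and inhibitors, integrins and adhesion, canonical Wnt targets, non-canonical Wnt and planar polarity, TGF-beta response, YAP and TEAD targets, and bone metastasis and osteoclast factors. Further lists were NF-kB and inflammatory cytokines, interferon response, MHC class I and antigen presentation, MAPK output and growth factor feedback, EGFR ligands and receptors, G1/S and DNA replication genes, G2/M and mitosis genes, hypoxia and glycolysis, ER stress and ATF4 targets, cholesterol synthesis, and angiogenesis factors. Markers of other cells were luminal androgen-responsive prostate, neuroendocrine, fibroblast and osteoblast, and leukocyte and endothelial markers. Mitochondrial genome transcripts, immediate early and heat shock genes, and ribosomal protein genes served as signs of RNA quality and handling. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists per comparison, and again with the correlation estimated per list. Only members that met the count minimum entered the main test, so list results cover those members alone. Each median was also placed among 10000 random lists of the same size matched on expression. Because the hairpin comparisons share their control libraries, their correlation and overlap are given beside values from 10 simulations of unchanged lines with the same controls.

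The test was checked on simulated counts for 9556 genes with the real means, library sizes and spread. Against control in sh718, it recovered 12% of 50 genes changed by 1.3-fold, 36% at 1.5-fold, 70% at 2-fold and 100% at 4-fold, with 2 false calls. For sh720 it recovered 14%, 48%, 70% and 98% of 50 genes at the same sizes, with 5 false calls. No gene was called between the simulated hairpin lines, which were alike.

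Neighbouring genes were examined along each chromosome after the first results were seen. Stretches were sought on every second tested gene as windows of 25 genes whose mean change went past the 95th percentile of the maxima of 200 shuffled gene orders, with single changes limited to 2 on the log2 scale and gaps of up to 10 genes joined, and were measured on the genes left out of the search. On simulated log2 changes of 9526 genes with 100 neighbours lowered, the stretch was found in 0 of 5 runs at a log2 lowering of 0.2, in 4 at 0.4 and in 5 at 0.6, and 1 of 5 runs with no lowering gave a window.

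Alternatives were DESeq2 1.42.0 as the test, DESeq2 size factors, total counts, no count minimum, a mean of at least 100, libraries thinned to the smallest total, a block for the replicate number, the rule of size, both hairpins as 1 arm, and each library left out in turn. Added after the data were seen were a minimum change of 1.5-fold, 2 lines at a time, nuclear protein-coding genes alone, removal of the trend with GC content and transcript length (known for 99.9% of tested genes), and genes outside the chromosome stretches.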

Results

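Gene expression was measured by RNA sequencing in 3 lines of PC3-Luc human prostate cancer cells, with 3 libraries per line. A control hairpin line was compared with 2 lines carrying short hairpins against CTHRC1, sh718 and sh720. The series is about CTHRC1, a secreted glycoprotein that promotes cell migration, and prostate cancer metastasis to bone. The comparisons ask which genes change when CTHRC1 is lowered, and whether both hairpins change the same genes. Library totals ran from 883663 to 1108960 counts, and the summed totals were 2909136 in control, 2891483 in sh718 and 2926839 in sh720. Mitochondrial genome transcripts held 12% to 16.4% of the counts of a library. On the first principal component, with 38.8% of the variance, the sh718 libraries lay at -30.7 to -29.5 and all others at 11.4 to 19.0. The second, with 16.8%, put sh720 at 15.3 to 16.5 and control at -19.6 to -16.

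CTHRC1 (ENSG00000164932, GRCh38 chromosome 8, 103371515 to 103382997, plus strand) was lower in both hairpin lines. Its level was 116 ± 16.4 CPM in control (SD, n = 3 libraries), 1.81 ± 0.672 in sh718 and 16 ± 5.48 in sh720. The log2 change was -5.91 in sh718 (SE 0.31, edgeR adjusted p 1.17e-25) and -2.86 in sh720 (SE 0.19, adjusted p 1.19e-19). From summed counts of 331, 5 and 47, sh718 retained 1.55% of the control level (exact 95% interval 0.500% to 3.65%) and sh720 retained 13.7% (9.85% to 18.6%). These intervals cover counting error only. The sh718 line held less CTHRC1 than the sh720 line, by a log2 difference of -3.05 (SE 0.51, adjusted p 2.5e-06).

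**Figure D1:**
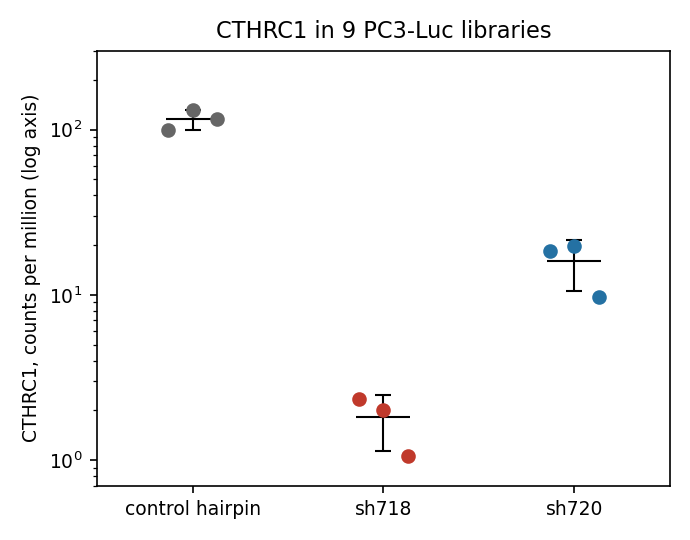
CTHRC1 level in CPM on a log axis for each library of the control, sh718 and sh720 lines, with points for libraries and a line with error bar for the mean and SD. The means were 116, 1.81 and 16 CPM.

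Genes higher in both hairpin lines included secreted peptides, lipid enzymes and a nuclear receptor. The incretin hormone gene GIP (ENSG00000159224, chromosome 17, 48958554 to 48968596) went from 5.85 ± 2.16 CPM to 40.9 ± 1.25 in sh718 (log2 2.76, SE 0.30, adjusted p 2.47e-11). In sh720 it reached 70.6 ± 6.01 (log2 3.54, SE 0.26, adjusted p 7.84e-18). TFF2 (ENSG00000160181, chromosome 21, 42346357 to 42351128), which encodes a mucosal trefoil peptide, went from 150 ± 6.29 CPM to 479 ± 48.2 (log2 1.68, SE 0.10, adjusted p 1.1e-23) and 317 ± 32.7 (log2 1.08, SE 0.10, adjusted p 9.91e-14). The fatty acid desaturase gene SCD5 rose by a log2 of 1.46 in sh718 and 1.47 in sh720, and the serine palmitoyltransferase gene SPTLC3 by 1.27 and 1.19. The retinoid X receptor gene RXRA rose by 1.38 and 1.49, the fucosidase gene FUCA2 by 1.45 and 1.16, and WDR72 by 2.16 and 3.02. BTBD9 rose by 1.74 in sh718 and by 1.54 in sh720, where the call was lost without sh720 library 1, control library 1 or control library 2 (adjusted p 0.0506 to 0.167). The histone gene H2AC20 was called by edgeR at 1.3 and 1.48, but its libraries varied widely (99.7 ± 73.5 CPM in control and 260.2 ± 192 in sh718), sh718 library 2 lay below every control library at 47.4 CPM, and DESeq2 called it in neither line (adjusted p 0.340 and 0.425). WDR72 was missed by DESeq2 in sh718 (adjusted p 0.0516).

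A few of the shared increases started near 0 counts. The zinc finger gene ZNF544 had 1 count over the control libraries, and its ratio of summed counts was 48.2 in sh718 (95% interval 8.24 to 1944) and 29.8 in sh720 (4.97 to 1216). The retinol carrier gene RBP4 had 2 control counts, with ratios of 14.9 (3.76 to 129) and 25 (6.59 to 212). EPB41L3, which encodes a protein linking membrane to cytoskeleton, had no control count and was at least 21.5-fold higher in sh718 and at least 4.49-fold higher in sh720.

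Genes lower in both hairpin lines included the growth factor gene MDK, the nucleolar gene GNL3, the centrosomal gene CEP78 and FJX1. FJX1 (ENSG00000179431, chromosome 11, 35618419 to 35620868) went from 103 CPM to 48.2 in sh718 and 43.7 in sh720 (log2 -1.11 and -1.25, SE 0.15 for both, adjusted p 2.06e-08 and 1.75e-09). MDK (ENSG00000110492, chromosome 11, 46380756 to 46383837) went from 112 CPM to 45.9 and 59.0 (log2 -1.26 and -0.91). GNL3 changed by -0.87 and -0.89, CEP78 by -1.14 and -1.23, and UQCRHL, an intronless relative of UQCRH, by -1.53 and -1.66. FJX1 and MDK lie in a chromosome 11 stretch whose genes were lower as a set in sh718, and GNL3 in a chromosome 3 stretch lower in sh720. Non-coding genes were also lower in both lines. MIR30A (ENSG00000207827, chromosome 6, 71403551 to 71403621), the precursor of a microRNA whose hairpin backbone is widely used as a scaffold in hairpin vectors, had summed counts of 355 in control, 13 in sh718 and 22 in sh720 (log2 -4.69 and -4.04). The vectors of the lines are not described in the sources used here, so these counts are assigned neither to the genomic gene nor to vector sequence. The host gene LINC00472 had 5, 4 and 4 counts. FP671120.7, a long non-coding RNA, changed by -3.82 and -2.82.

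Pseudogenes made up part of the shared decreases. MTCO2P12 (ENSG00000229344, chromosome 1, 632757 to 633438), a nuclear copy of the mitochondrial gene MT-CO2, fell from 184 ± 12.4 CPM to 2.46 in sh718 and 4.38 in sh720 (log2 -6.13 and -5.36, adjusted p 6.45e-32 and 1.7e-31). MTND1P23, a nearby copy of MT-ND1, changed by -1.33 and -4.28. Both match their mitochondrial parents over runs of 108 and 158 identical bases, longer than the reads of 75 bp. The processed pseudogene AC073861.1 changed by -1.13 and -1.71. AC018868.1, another, had summed counts of 64 in control and 3 in sh718 (ratio of control over sh718 20.8, 95% interval 6.81 to 104), and was at least 22.2-fold lower in sh720, with no count. Of the 24 genes named as higher or lower in both lines, CTHRC1 among them, all but H2AC20 (23) had every sh718 library beyond all control libraries and 24 had every sh720 library so. Chance fully separates 3 libraries from 3 in 10% of genes, and these genes were chosen among called ones.

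Both lines shared 217 called genes, 82 higher and 135 lower, against 66.7 if the lists of calls were independent. Another 93 genes were called in opposite directions, also against 66.7 if the lists were independent. DESeq2 called 34 and 63 in both and 40 in opposite directions. Without sh720 library 2 the genes higher in both came to 52, and without control library 3 to 54. Without control library 1, 2 or 3 the opposite genes came to 54, 60 and 57. Of the shared genes, 66 also differed between the hairpins. At 2-fold or more in both lines, 15 genes were higher and 12 lower, among them 1 and 5 pseudogenes. Across genes, which are not independent replicates, the changes in the hairpin lines had a Pearson r of 0.286 and a Spearman rho of 0.240. Simulated unchanged lines with the same controls gave 0.502 and 0.470, since shared controls alone make changes resemble each other. The covariance was 0.0638 against 0.0332 in those simulations, and 58.5% of genes had changes of the same sign against 66.7%. No gene was called in both lines in 10 simulations.

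**Figure D2:**
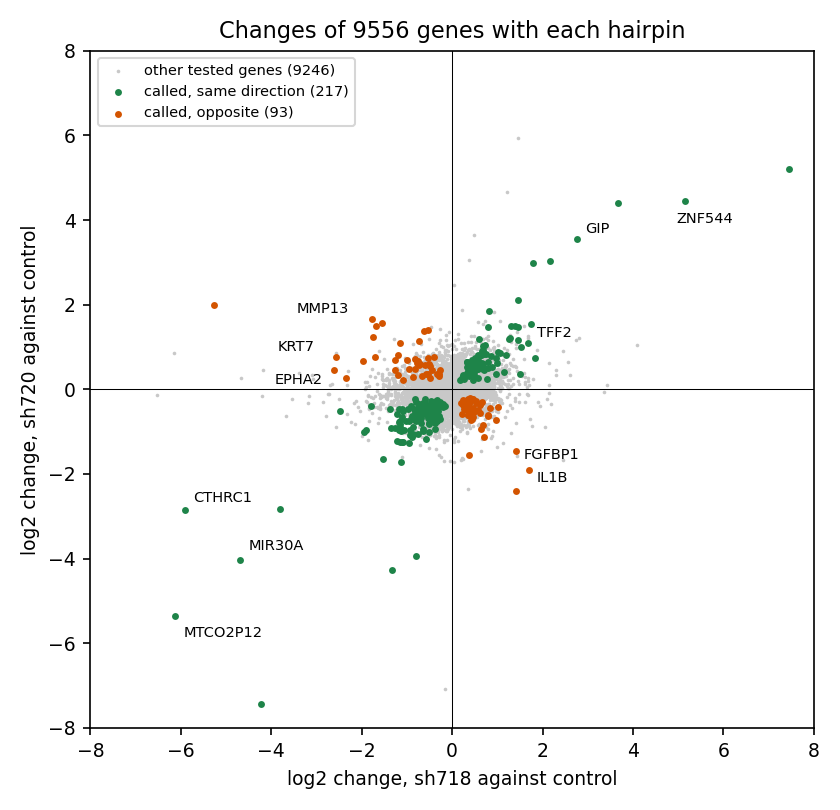
Log2 change in sh720 against control (vertical axis) plotted against log2 change in sh718 against control (horizontal axis), 1 point per tested gene, coloured by whether the gene was called in both lines in the same direction or in opposite directions. The 217 genes called alike and the 93 called in opposite directions are set apart, and fitted changes of genes with 0 to 3 counts in a line depend on the prior count.

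Neighbouring genes moved together along parts of some chromosomes. In sh718, genes were lower as a set on chromosome 3 from 10115592 to 38255488 (75 genes, held-out median log2 -0.58), chromosome 5 from 10249921 to 44820428 (61 genes, -0.30), chromosome 8 from 90621995 to 100259278 (35 genes, -0.19) and chromosome 11 from 14504874 to 62592177 (129 genes, -0.41). In sh720 they were lower on chromosome 3 from 48517684 to 53256052 (71 genes, -0.40) and chromosome 10 from 70815961 to 80205572 (45 genes, -0.44). The sh720 stretches lay at -0.36 and -0.43 in sh718. Both comparisons use the same control libraries, so a higher level in the control line alone would lower both, and neither stretch was found in sh718 against sh720. The sh718 stretches on chromosomes 3, 5 and 11 lay at 0.07, -0.04 and -0.03 in sh720. The chromosome 8 stretch lay at -0.14 in sh720, and 39.9% of the median was kept once a trend with GC content and length was removed. These stretches held 45 of the 135 genes lower in both lines (33.3%) and 0 of the 82 higher ones, against 417 (4.36%) of all tested genes, an excess partly fixed by the choice of stretches with lower genes. Between the hairpins, 5 stretches were found. Those on chromosomes 3, 5 and 11 that overlap the ones against control had held-out medians of -0.55, -0.28 and -0.44, or -0.50, -0.17 and -0.40 with the trend removed. That on chromosome 8 had -0.06, or 0.07 with the trend removed, so the held-out genes do not show it lower in sh718. The fifth, on chromosome 11 from 87037844 to 117098437 (73 genes, -0.48, or -0.34), was not found by the search against control. Its held-out library medians relative to control were nonetheless -0.398 to -0.351 in sh718, and -0.007 to 0.124 in sh720. MMP13 lies in this stretch.

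**Figure D3:**
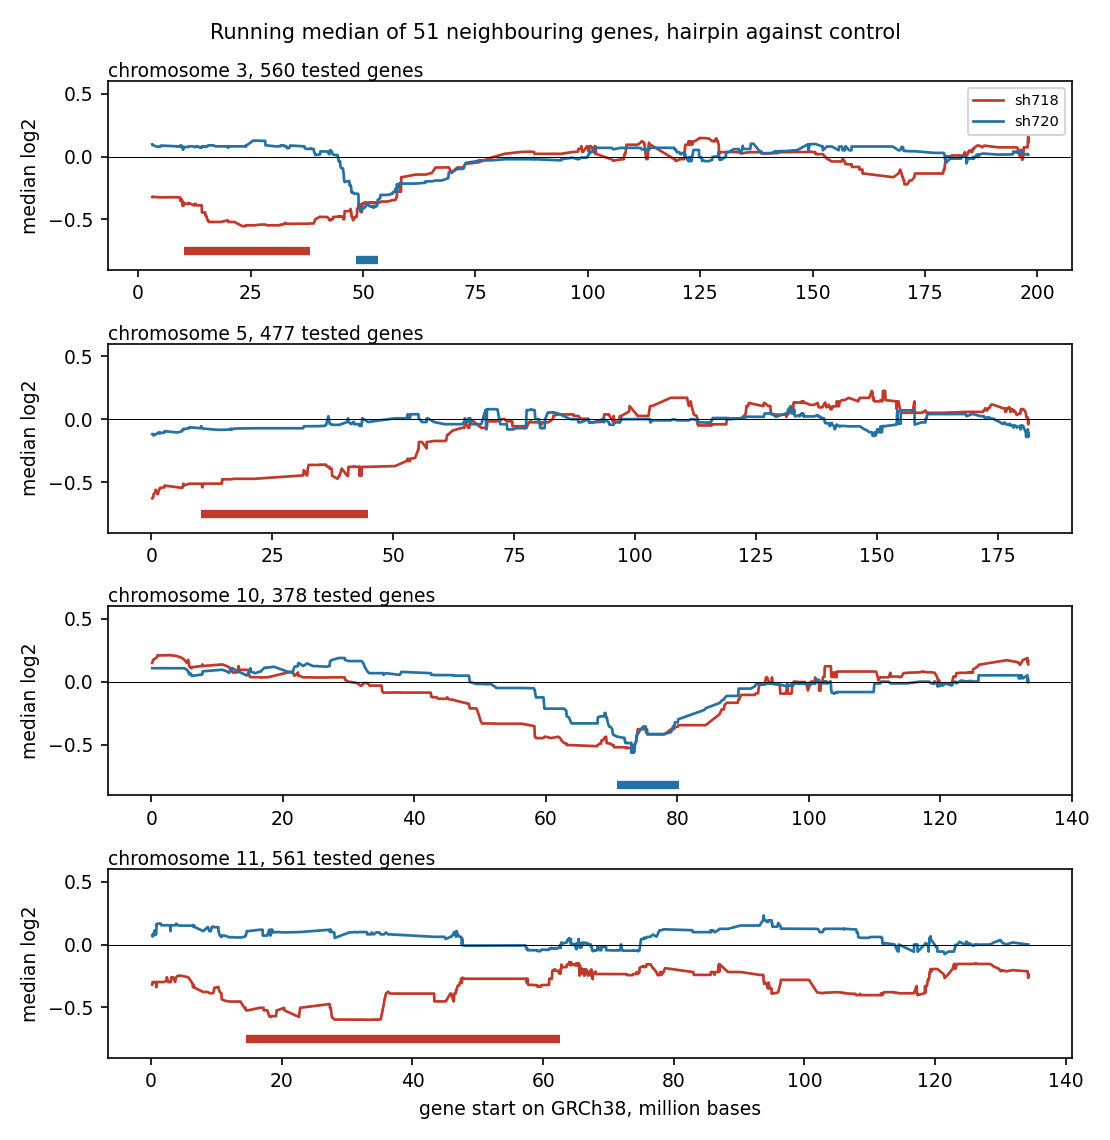
Running median log2 change of 51 neighbouring tested genes along chromosomes 3, 5, 10 and 11 in GRCh38 position, with lines for sh718 and sh720 against control and bars for the stretches found. The held-out medians of the barred stretches ran from -0.58 to -0.30.

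In sh718 against control, keratin 81, the scaffold gene AKAP12, the bone morphogenetic protein inhibitor NOG and ITGB4 were higher, while KRT7, EPHA2 and the Wnt inhibitor DKK1 were lower. KRT81, chosen after its values were seen, went from 1828 ± 65.0 CPM to 8137 ± 210.5 (log2 2.15, SE 0.06, adjusted p 1.61e-41), and stood at 1712 ± 96.7 in sh720 (log2 -0.09). AKAP12, chosen likewise, went from 263 ± 36.5 CPM to 1167 ± 123 (log2 2.14, SE 0.08, adjusted p 6.93e-33). NOG rose from 145 ± 4.65 CPM to 402 ± 27.1 (log2 1.47, SE 0.10, adjusted p 1.05e-20) and DKK1 fell from 1992 ± 152 to 944 ± 64.5 (log2 -1.08, SE 0.07, adjusted p 3.16e-22). In all, 914 genes were higher and 1033 lower, of 9556 tested. DESeq2 called 447 and 561. Of 10 possible splits of these 6 libraries, too few for a test, the real one gave 1947 calls and the highest other 1. At least 2-fold changes numbered 154 higher and 284 lower.

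In sh720 against control, TRIB3, STC2, PLAT and the cystine transporter gene SLC7A11 were higher, while PLAU and the chaperone gene HSPA8 were lower. TRIB3, which encodes a stress-induced pseudokinase, rose by a log2 of 1.40 (SE 0.09, adjusted p 4.42e-21) and the hormone gene STC2 by 1.18 (SE 0.08, adjusted p 8.09e-20). PLAU, which encodes urokinase, fell from 334 CPM to 171 (log2 -0.97, SE 0.10, adjusted p 1.48e-12) and HSPA8 from 402 to 260.5 (log2 -0.63, SE 0.09, adjusted p 7.65e-08). Whether PLAU lies in a chromosome stretch lower in sh720 was not looked up. In all, 328 genes were higher and 327 lower. DESeq2 called 132 and 166, and without control library 3 the higher genes came to 218. Of 10 possible splits, again too few for a test, the real one gave 655 calls and the highest other 0. At least 2-fold changes numbered 66 higher and 49 lower.

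Several hypoxia and glycolysis genes were higher in both lines. The phosphoglycerate kinase gene PGK1 went from 1317 ± 45.5 CPM to 2572 ± 29.6 in sh718 (log2 0.97, SE 0.06, adjusted p 4.25e-22) and 2203 ± 67.9 in sh720 (log2 0.74, SE 0.06, adjusted p 2.4e-16). BNIP3 rose by 0.72 and 0.46 and ENO1 by 0.48 and 0.30. ENO2 rose by 0.88 and 0.54, the latter lost without sh720 library 2 or 3 or any control library (adjusted p 0.0671 to 0.224). Of 20 tested members, 12 rose and 1 fell in sh718, and 6 rose and 1 fell in sh720, or 14 and 7 called when adjusted over the list alone. The list median was 0.67 in sh718 (camera adjusted p 4.94e-06) and 0.22 in sh720 (2.87e-06), with 0.102 and 0.107 when the correlation was estimated. HK2 rose by 1.06 and SLC2A1 by 0.73 in sh718. LDHA rose by 0.46 in sh720 and lay at 0.08 in sh718, where it was called at 0.19 once the GC and length trend was removed (adjusted p 0.00762). The member that fell in sh718 was GAPDH (-0.73), with 868 counts over all libraries. How reads were counted is not given in the sources used here.

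**Figure D4:**
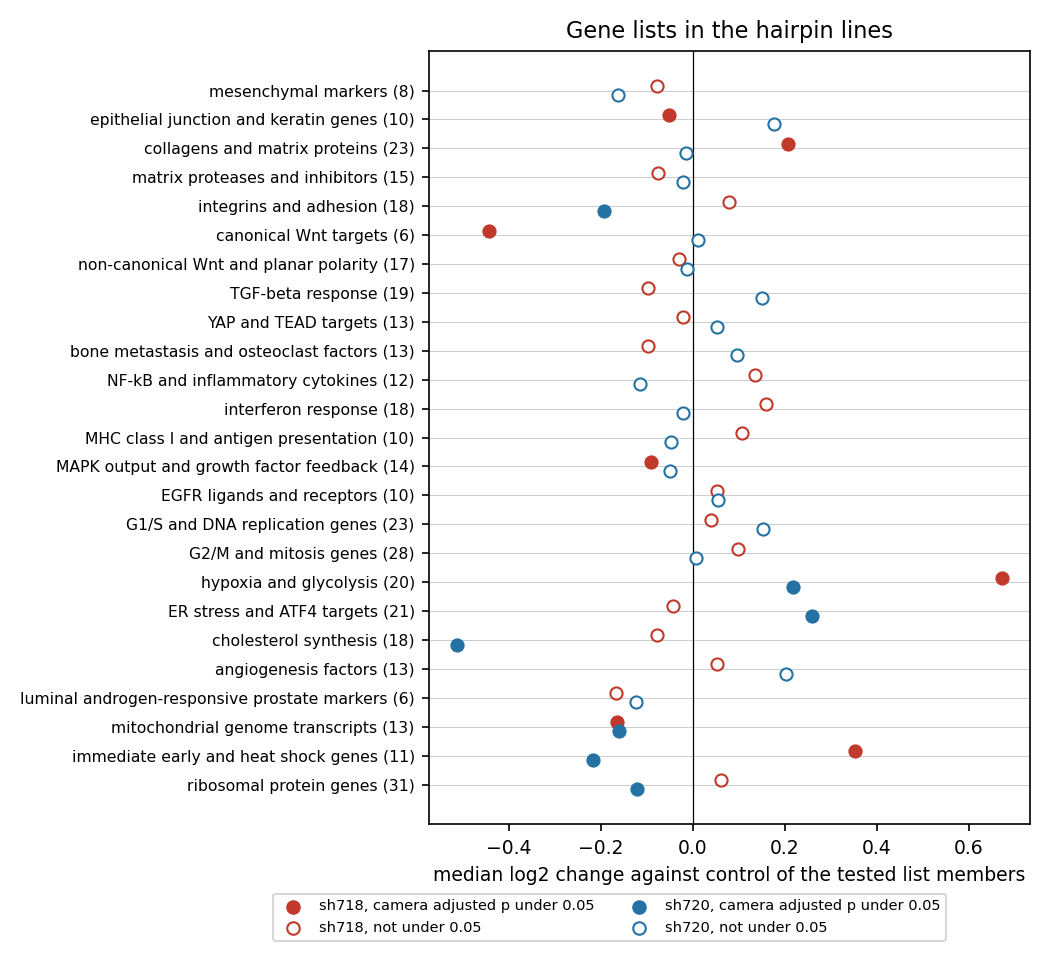
Median log2 change of the tested members of each gene list (horizontal axis) in sh718 and sh720 against control, 1 point per list and line, with filled points for lists called by camera at the preset correlation. Hypoxia and glycolysis lay at 0.67 and 0.22, and cholesterol synthesis at -0.08 and -0.51.

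Cholesterol synthesis genes were lower in sh720. INSIG1 fell by 1.64 on the log2 scale (SE 0.29, adjusted p 2.04e-05). Of 18 tested members 6 fell and none rose in sh720, or 10 called when adjusted over the list alone, and the median was -0.51 (camera adjusted p 2.01e-07, or 0.0196 with estimated correlation). In sh718, 1 rose and 1 fell, 2 when adjusted over the list alone, with a median of -0.08 (0.891). DHCR7 was the member lower in both, at -0.57 and -0.52, though DESeq2 called it in neither line (adjusted p 0.0752 and 0.211). Its call was lost in sh718 without control library 3 (adjusted p 0.0605), and in sh720 without sh720 library 2 or 3 or control library 2 or 3 (0.0506 to 0.212).

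Some genes of the endoplasmic reticulum stress response moved apart, with 5 of 21 tested members called in opposite directions. TRIB3 and CEBPB rose in sh720 (1.40 and 0.71) and fell in sh718 (-0.54 and -0.82), whereas the chaperone genes HSPA5 and HSP90B1 rose in sh718 (0.62 and 0.57) and fell in sh720 (-0.37 and -0.49). MANF, in the chromosome 3 stretch of sh720, fell in both (-0.37 and -0.94). Of 21 tested members, 4 rose and 4 fell in sh718, and 8 rose and 5 fell in sh720, or 8 and 16 called when adjusted over the list alone. The medians were -0.04 (camera adjusted p 0.898) and 0.26 (0.00332, or 0.373 with estimated correlation). SLC7A11 (1.28), SESN2 (0.95) and DDIT4 (0.75) rose in sh720, and the serine synthesis gene PSAT1 fell by 1.58 in sh718.

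Immediate early and heat shock genes, also a sign of handling, were higher in sh718 and lower in sh720. HSP90AA1 changed by 0.35 and -0.36, HSPA8 by 0.43 and -0.63, and JUN by 1.13 in sh718. Of 11 tested members, 8 rose in sh718 and 5 fell in sh720, or 9 and 7 called when adjusted over the list alone. The medians were 0.35 (camera adjusted p 1.18e-05, or 0.0531 with estimated correlation) and -0.22 (2.76e-05, or 0.0387). They moved with the chaperones above.

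**Figure D5:**
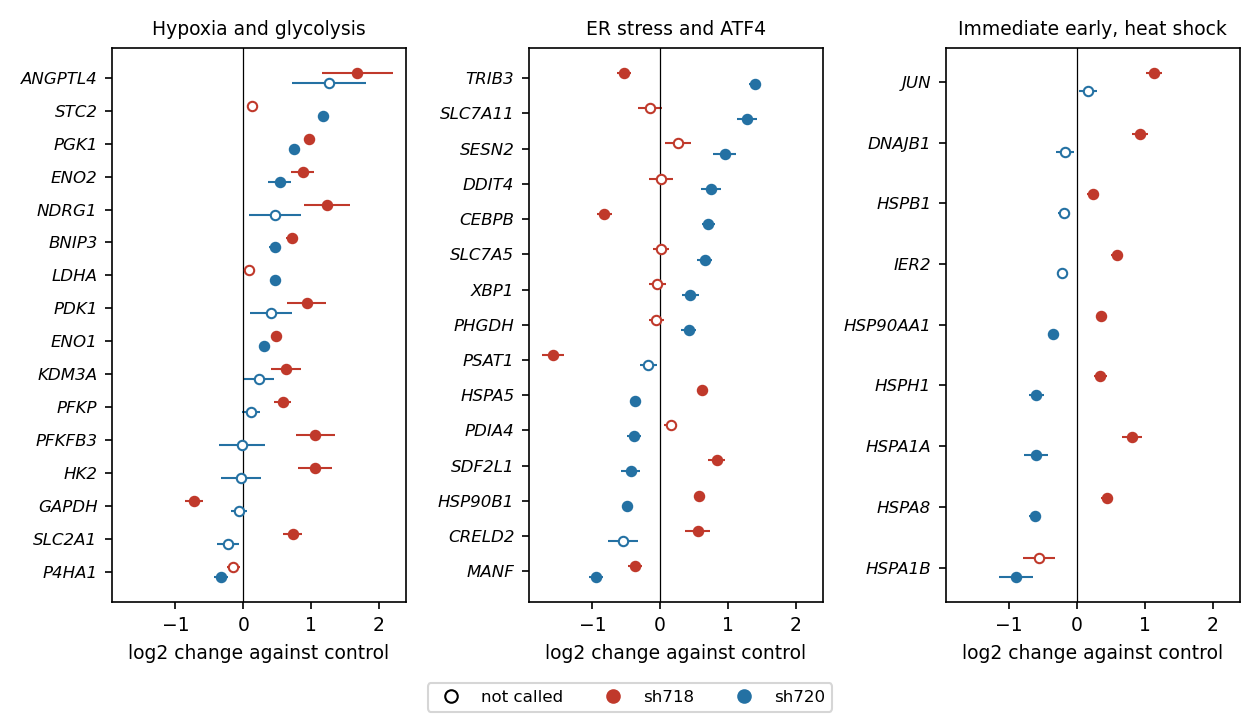
Log2 change against control (horizontal axis) of the members of 3 lists that were called in at least 1 hairpin line, with a panel each for hypoxia and glycolysis, ER stress and ATF4 targets, and immediate early and heat shock genes. Points are sh718 and sh720, bars the SE and filled points called changes, such as PGK1 at 0.97 and 0.74 and HSPA8 at 0.43 and -0.63.

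Several mitochondrial genome transcripts were lower in both lines. MT-ND1 changed by -0.83 and -0.64, MT-ND3 by -0.59 and -0.36 and MT-CO1 by -0.36 and -0.51, the last missed by DESeq2 (adjusted p 0.206 and 0.067). MT-CYB changed by -0.47 and -0.27, the latter lost without sh720 library 3 (adjusted p 0.0666). Of 13 members, 1 rose and 8 fell in sh718, and 6 fell in sh720, or 9 and 8 called when adjusted over the list alone. The medians were -0.16 in both (camera adjusted p 2.05e-04 and 4.77e-07, or 0.223 and 0.116 with estimated correlation). In sh718 the median was 0.06 once the GC and length trend was removed (0.578). Of 31 ribosomal protein genes, 9 rose and 6 fell in sh718 (median 0.06, camera adjusted p 0.315, or 0.12 and 0.00104 with the GC and length trend removed, 17 adjusted over the list alone), and 8 fell in sh720 (median -0.12, 5.55e-06, or 0.396 with estimated correlation, 14 adjusted over the list alone). RPLP0 lay at 0.02 and -0.11 and RPL8 at -0.02 and -0.11, uncalled.

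Among matrix and adhesion genes, COL6A1 rose in both lines (0.63 and 0.51, adjusted p 6.67e-10 and 6.28e-07), while ITGA1 (-0.82 and -0.70) and VCL (-0.52 and -0.80) fell in both. VCL lies in the chromosome 10 stretch of sh720. ITGB4 rose by 1.51 in sh718 and 0.35 in sh720, the latter lost without sh720 library 2 or 3 or control library 2 or 3 (adjusted p 0.0674 to 0.125). ZYX fell in both (-0.34 and -0.26), the latter lost without sh720 library 1 or 3 or control library 2 or 3 (0.0715 to 0.113). Of 23 collagen and matrix genes, 8 rose and 1 fell in sh718 (median 0.21, camera adjusted p 0.0115, or 0.102 with estimated correlation), and 1 rose and 2 fell in sh720 (-0.02, 0.923), or 10 and 9 called when adjusted over the list alone. SPARC rose by 1.70 and LAMA5 by 0.84 in sh718. Of 18 integrin and adhesion genes, 5 rose and 5 fell in sh718 (median 0.08, 0.529), and 1 rose and 4 fell in sh720 (-0.19, 0.0108, or 0.237 with estimated correlation, 0.0566 without control library 3 and 0.0589 outside the chromosome stretches). Adjusted over the list alone, 11 and 5 were called. Of 15 matrix protease genes, 5 rose and 3 fell in sh718 (median -0.08) and 4 rose and 2 fell in sh720 (-0.02), or 9 and 6 adjusted over the list alone. Their camera direction was up where the medians were negative (0.164 and 0.637). TIMP1 rose by 0.65 in sh718, and PLAT by 0.69 in sh720.

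The tested mesenchymal and epithelial genes did not shift as sets in both lines. In the main fit, 7 of 15 listed mesenchymal genes and 11 of 21 listed epithelial genes were not tested. FN1 fell by 1.01 in sh718 and by 0.74 in sh720, the latter lost without control library 3 (adjusted p 0.0660) and with DESeq2 (0.0714), and the cadherin gene CDH11 changed by -0.59 and -0.44. Of 8 tested mesenchymal genes, 2 rose and 3 fell in sh718 (median -0.08, camera adjusted p 0.476), and 1 rose and 2 fell in sh720 (-0.16, 0.637), with 5 and 5 adjusted over the list alone. KRT7 fell in sh718 (-2.57, SE 0.12, adjusted p 7.42e-28) and rose in sh720 (0.75, SE 0.08, adjusted p 1.62e-10). KRT19 rose by 0.39 in sh718, and KRT18 by 0.22 in sh720, lost without sh720 library 1 or 2 or control library 1 or 3 (0.0888 to 0.195). EPCAM fell by 1.39 in sh718. Of 10 tested epithelial genes, 2 rose and 3 fell in sh718 (median -0.05, camera 0.0217, or 0.321 with estimated correlation), and 4 rose and 1 fell in sh720 (0.18, 0.0565), with 6 and 7 adjusted over the list alone. The sh718 list call was lost without sh718 library 1 or 3 or control library 1 (0.0529 to 0.0660), with no count minimum (median -0.29, 0.150) and with a mean of at least 100 (-0.01, 0.262). The sh720 list was called under 10 alternatives (0.0118 to 0.0498).

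Some canonical Wnt targets were lower in sh718, though 12 of the 18 listed were not tested in the main fit. MYC fell by 0.59 and CD44 by 0.47, besides DKK1, while CCND1 stood at -0.02 in sh718 and -0.05 in sh720. Whether CD44 lies in a chromosome stretch lower in sh718 was not looked up. Of 6 tested canonical targets, 3 fell in sh718 (median -0.44, camera adjusted p 2.82e-04, or 0.0725 with estimated correlation) and 1 rose in sh720 (0.01, 0.923), 3 and 1 adjusted over the list alone. The riser was DKK1 at 0.22, lost without sh720 library 1 or 2 or control library 1 or 3 (0.0677 to 0.181). Of 17 non-canonical Wnt genes, 1 rose and 2 fell in sh718 (-0.03, 0.891), and 1 rose and 1 fell in sh720 (-0.01, 0.996), 3 and 2 adjusted over the list alone. RHOA, in the chromosome 3 stretch of sh720, fell there by 0.43 and in sh718 by 0.19, the latter lost without sh718 library 2 or 3 or control library 2 or 3 (0.0629 to 0.126) and at -0.11 with the GC and length trend removed (0.255). In the TGF-beta list ID1 rose (0.64 and 0.80) and ID2 fell (-0.59 and -1.16), with ID2 missed by DESeq2 in sh718 (0.0504). Of its 19 tested members, 2 rose and 4 fell in sh718 (median -0.10, camera direction up, 0.891), and 3 rose and 2 fell in sh720 (0.15, 0.248), 6 and 6 adjusted over the list alone. Of 13 YAP and TEAD targets, 2 rose and 3 fell in sh718 (-0.02, 0.898), and 2 rose and 2 fell in sh720 (0.05, camera direction down, 0.923), 5 and 5 adjusted over the list alone. FJX1 alone fell in both.

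Of the 32 bone metastasis and osteoclast factors listed, 19 were not tested in the main fit. None of the tested ones was called in the same direction in both lines, and DKK1 was called in opposite directions. Of 13 tested members, 2 rose and 1 fell in sh718 (median -0.10, camera direction up, adjusted p 0.891), and 3 rose and 1 fell in sh720 (0.10, 0.898), 3 and 5 adjusted over the list alone. CXCL8 rose by 0.83 in sh720. Of 12 NF-kB and cytokine genes, IL1B rose in sh718 as the sole call (median 0.13, 0.575), and CXCL8 rose and IL1B fell in sh720 (-0.12, 0.923), 1 and 2 adjusted over the list alone. NFKBIA (0.17 and -0.33) and SOD2 (-0.23 and -0.28) were uncalled. Of 18 interferon genes, 1 rose and 2 fell in sh718 (0.16, 0.597), and 1 fell in sh720 (-0.02, 0.923), 3 and 1 adjusted over the list alone. ISG20 rose by 2.14 and IFITM3 fell by 0.47 in sh718, and ISG15 fell by 0.30 in sh720, lost without sh720 library 3 or any control library (0.0568 to 0.262). Of 10 MHC class I genes, 2 rose and 3 fell in sh718 (0.11, 0.891), and 1 fell in sh720 (-0.05, camera direction up, 0.923), 5 and 3 adjusted over the list alone. B2M fell by 0.18 in sh718, lost without any 1 of 5 libraries, which were all of sh718 and control libraries 2 and 3 (0.0645 to 0.127), and lay at -0.03 with the GC and length trend removed (0.827).

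Among growth factor genes in sh718, EPHA2 fell by 2.35 (SE 0.11, adjusted p 2.37e-27), SPRED1 by 0.64 and the EGFR ligand gene AREG by 1.37, while HBEGF rose by 1.34 and AXL by 0.72. FOSL1 (0.05 and -0.00) and PHLDA1 (-0.14 and -0.03) were uncalled, as was MET (-0.07 and 0.22). Of 14 tested MAPK output genes, 4 fell in sh718 (median -0.09, camera adjusted p 0.0115, or 0.135 with estimated correlation), and 2 rose in sh720 (-0.05, 0.923), 5 and 2 adjusted over the list alone. Of 10 EGFR ligand and receptor genes, 3 rose and 1 fell in sh718 (0.05, 0.318), and 1 fell in sh720 (0.05, camera direction down, 0.855), 4 and 4 adjusted over the list alone. Among 13 angiogenesis factors, VEGFB fell by 1.01, VEGFC by 0.91 and PDGFB by 1.57 in sh718, and NRP1 rose by 0.43 in sh720. Of these 13, 1 rose and 4 fell in sh718 (median 0.05, camera direction down, 0.326), and 1 rose in sh720 (0.20, 0.0727), 5 and 2 adjusted over the list alone.

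Cell cycle genes changed little as sets. The ribonucleotide reductase gene RRM2 rose in both lines (0.60 and 0.50, adjusted p 2.84e-07 and 2.87e-05). Of 23 tested G1/S genes, 4 rose and 3 fell in sh718 (median 0.04, camera adjusted p 0.575), and 2 rose in sh720 (0.15, 0.108), 7 and 3 adjusted over the list alone. Of 28 G2/M genes, 4 rose and 1 fell in sh718 (0.10, 0.254), and 1 fell in sh720 (0.01, camera direction down, 0.923), 5 and 3 adjusted over the list alone. CENPF (0.18 and 0.06) and UBE2C (0.09 and -0.03) were uncalled, though UBE2C was called in sh718 at 0.26 with the GC and length trend removed (0.0130), and CCNB1 fell by 0.61 in sh720. Of markers of other cells, none of 6 luminal prostate genes was called (medians -0.17 and -0.12, camera 0.597 and 0.923, the latter with direction up), or 0 and 3 adjusted over the list alone, HOXB13 lying at -0.17 and -0.24 and PMEPA1 at -0.17 and 0.44, the latter called under 6 alternatives (0.0291 to 0.0464). Of 2 tested neuroendocrine genes ENO2 was called (medians 0.47 and 0.51), and no fibroblast or osteoblast marker had enough counts for the test. The sole tested leukocyte and endothelial marker, PECAM1, rose by 1.03 in sh718 and lay at -0.28 in sh720.

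Between the hairpin lines, sh718 expressed more of the actin-bundling gene LCP1, the interleukin gene IL1B and the receptor gene IL1RL1. The long non-coding RNA AC137932.2 was also higher in sh718. Lower in sh718 were the neuropeptide gene GAL, the inflammasome adaptor gene PYCARD, PDE3B and the transcription factor gene GATA2. LCP1 was at least 15.6-fold higher in sh718, with no count in sh720. IL1RL1 had 3 counts in sh720 (ratio 19.5, 95% interval 6.34 to 97.6), and AC137932.2 had a ratio of 16 (5.13 to 80.4). GAL, PYCARD and PDE3B had no count in sh718 and were at least 18.5-fold, 15.3-fold and 10-fold higher in sh720, and at least 4.55-fold, 8.45-fold and 11.1-fold higher in control. PDE3B lies in the chromosome 11 stretch of sh718. GATA2 had 1 count in sh718, with a ratio of 41.3 for sh720 over sh718 (7.04 to 1668). PTMAP2, a processed pseudogene 99% identical to PTMA over the aligned bases, was lower in sh718 than in sh720 (log2 -4.48, SE 0.37, adjusted p 3.57e-16). MTND1P23 was higher in sh718 by 2.95 (SE 0.12, adjusted p 1.12e-30). In all, 1173 genes were higher and 1246 lower in sh718 than in sh720, 25.3% of those tested. DESeq2 called 632 and 661. Of 10 possible splits, too few for a test, the real one gave 2419 and the highest other 0.

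Several genes went in opposite directions from control. IL1B went from 15.8 ± 6.27 CPM to 50.1 ± 2.71 in sh718 and 4.01 ± 1.89 in sh720 (log2 1.69 and -1.90, SE 0.25 and 0.43, adjusted p 1.2e-07 and 0.00138). FGFBP1, which encodes a carrier of fibroblast growth factors, changed by 1.41 and -1.46 (adjusted p 2.85e-10 and 1.86e-05). The collagenase gene MMP13 changed by -1.77 and 1.66 (adjusted p 0.00397 and 4.35e-06) and the kinesin gene KIF5C by -1.74 and 1.23 (adjusted p 0.000834 and 0.00026). GAL, with no count in sh718 and higher in sh720 than in control, was the fifth. AC137932.2 also went both ways (log2 1.42 in sh718, and a ratio of control over sh720 of 5.89, 95% interval 1.70 to 31.4, from 3 counts in sh720), lost in sh718 without control library 1 (adjusted p 0.0546) and in sh720 without sh720 library 1 or 2 (0.174 to 0.178).

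List medians also differed between the hairpins. Immediate early and heat shock genes were higher in sh718 than in sh720 by a median of 0.80 (camera adjusted p 9.12e-13, or 0.00525 with estimated correlation). Only this list held with estimated correlation, and the further ones called lay at 0.0656 to 0.470. Collagens and matrix proteins (0.45, 0.00863), cholesterol synthesis (0.36, 0.00149), integrins and adhesion (0.24, 0.0103) and ribosomal protein genes (0.22, 2.78e-05) were also higher in sh718. Lower in sh718 were angiogenesis factors (-0.48, 0.0157), endoplasmic reticulum stress genes (-0.45, 0.0459), canonical Wnt targets (-0.41, 6.49e-04), epithelial genes (-0.35, 5.73e-04) and MAPK output genes (-0.13, 0.0351). The endoplasmic reticulum stress call was lost without sh718 library 1 or 3 (0.107 to 0.214), and the MAPK call without sh718 library 1 or 2 or sh720 library 2 (0.0590 to 0.0835). The angiogenesis median was -0.10 with no count minimum (0.146). With a mean of at least 100 the collagen (0.0666), cholesterol (0.0666), integrin (0.0917), MAPK (0.0917) and endoplasmic reticulum stress (0.120) calls were lost. The remaining lists were uncalled between the hairpins.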

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

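The tests of explanations given here were all chosen after the results were seen, whereas the comparison of the hairpin lines was planned. A result was set apart for a closer look when sh718 and sh720 differed in that comparison, by edgeR for a gene or by camera for a list. Groups of 3 libraries are too small for a check of single libraries that stand apart. Values are log2 differences, sh718 minus sh720.

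CTHRC1 itself differed by -3.05, with less of it in sh718. Of the genes higher in both lines against control, EPB41L3 differed by 2.23, GIP by -0.79 and TFF2 by 0.60. Of those lower in both, MTND1P23 differed by 2.95 and AC073861.1 by 0.59. Genes higher in sh718 were LCP1 (6.93), IL1RL1 (4.12), AC137932.2 (3.84), IL1B (3.59) and FGFBP1 (2.87). Genes lower in sh718 were GAL (-7.26), PYCARD (-6.99), PDE3B (-6.38), GATA2 (-4.93), PTMAP2 (-4.48), MMP13 (-3.43) and KIF5C (-2.97). For LCP1, IL1RL1, AC137932.2, GAL, PYCARD, PDE3B and GATA2, with 0 to 3 counts in sh718 or sh720, the fitted value depends on the prior count.

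Members of the gene lists differed as well. Higher in sh718 were NOG (1.76), PECAM1 (1.31), ITGB4 (1.15), HSPA8 (1.06), TIMP1 (0.83), AXL (0.75), HSP90AA1 (0.72), ID2 (0.58), MANF (0.57) and NFKBIA (0.50). Smaller differences of this kind were found in VCL (0.28), KRT19 (0.25), BNIP3 (0.25), RHOA (0.23), PGK1 (0.22) and ENO1 (0.18). Lower in sh718 were DKK1 (-1.29), VEGFB (-1.05), PMEPA1 (-0.60), PLAT (-0.56), IFITM3 (-0.43), NRP1 (-0.43), MET (-0.29), MT-ND3 (-0.24), MT-CYB (-0.20) and MT-ND1 (-0.19). Leaving out 1 library lost the call for AC073861.1, KRT19, VCL, ID2, NFKBIA, MET, BNIP3, ENO1, MT-ND1, MT-ND3 and MT-CYB, with adjusted p of 0.0525 to 0.165, though each kept its sign, at sizes of 0.13 to 0.52. The libraries were sh718 3 or sh720 2 for AC073861.1, sh718 2 for KRT19, sh718 3 or sh720 1 for VCL, NFKBIA and MET, and sh718 1 or sh720 1 for ID2 and MT-CYB. They were sh718 1 or sh720 2 or 3 for BNIP3, sh718 2 or sh720 2 or 3 for ENO1, sh718 3 or sh720 1 or 2 for MT-ND1, and sh720 1 for MT-ND3. With the GC and length trend removed, the differences of MT-ND3 (-0.036), MT-CYB (-0.041) and MT-ND1 (-0.028) were no longer called (adjusted p 0.667 to 0.783). MET lost its call there too (-0.22, adjusted p 0.0506). With total counts alone, the calls of RHOA (0.0865), VCL (0.0604), BNIP3 (0.128) and ENO1 (0.155) were lost.

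Genes named after their values were seen differed too. Higher in sh718 were AC107956.1 (3.15), KRT81 (2.25), AKAP12 (2.05), INSIG1 (1.89), SPARC (1.61), ISG20 (1.53), HK2 (1.08), HSP90B1 (1.06), HSPA5 (0.99), JUN (0.97), LAMA5 (0.95), SLC2A1 (0.95), PLAU (0.81) and CCNB1 (0.66). Lower in sh718 were KRT7 (-3.33), EPHA2 (-2.62), TRIB3 (-1.94), CEBPB (-1.53), EPCAM (-1.48), SLC7A11 (-1.42), PSAT1 (-1.41), PDGFB (-1.25), STC2 (-1.05), AREG (-1.01), EEF1A1 (-0.92) and VEGFC (-0.90). Further ones were DDIT4 (-0.74), CXCL8 (-0.70), SESN2 (-0.69), CD44 (-0.67), GAPDH (-0.66), SPRED1 (-0.59), LDHA (-0.38) and MYC (-0.33). The call of MYC was lost without sh718 library 2 or 3 or sh720 library 2 (adjusted p 0.0594 to 0.0920), and CXCL8 lay at -0.42 with the GC and length trend removed (0.0520).

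List medians differed by 0.80 for immediate early and heat shock genes, 0.45 for collagens and matrix proteins, 0.36 for cholesterol synthesis, 0.24 for integrins and adhesion and 0.22 for ribosomal protein genes. They differed by -0.48 for angiogenesis factors, -0.45 for ER stress and ATF4 targets, -0.41 for canonical Wnt targets, -0.35 for epithelial junction and keratin genes and -0.13 for MAPK output and growth factor feedback. With the correlation between genes estimated, only the heat shock list held (camera adjusted p 0.00525), and the others lay at 0.0656 to 0.470. The ER stress difference was lost without sh718 library 1 or 3 (0.107 to 0.214), and the MAPK difference without sh718 library 1 or 2 or sh720 library 2 (0.0590 to 0.0835).

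Among nuclear copies of mitochondrial genes on chromosome 1 were some of the largest decreases of both lines. A single change in transcription of the whole block is argued against only as the whole account of the counts. The log2 changes of its 5 tested members spread over at least 5.83 in each line. If mitochondrial reads were placed on some members, such a spread cannot tell how the block itself was transcribed. Lower mitochondrial transcripts overall are argued against for MTCO2P12, since its parent MT-CO2 changed by -0.21 at most. For MTND1P23 they are argued against as the whole account only. Its parent MT-ND1 fell too (-0.83 in sh718 and -0.64 in sh720), but MTND1P23 changed by -0.50 beyond it in sh718 (SE 0.10) and -3.64 in sh720 (SE 0.13). Placement of mitochondrial reads on near-identical copies remains open as a hypothesis and may depend on base differences between the lines, which were not examined. The identical runs that it needs are present, 108 bases at least against reads of 75 bp. MTND6P4, a copy of MT-ND6 on chromosome 5 picked after its values were seen, went the other way in sh720. Its level was 0.751 CPM in control, 1.81 in sh718 and 20.9 in sh720, and its longest identical run was 91 bases.

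Genes called in opposite directions numbered 93 of the 655 called in sh720. A single response graded with the loss of CTHRC1 is argued against as the whole account, since it could give few such genes, and 5% of the sh720 calls would be 32.8. A trend with GC content or transcript length is argued against, since 91 such genes were called once the trend was removed. Effects of each hairpin on other transcripts, and divergence of the lines in culture, stay open and were not tested. With 1 line per hairpin, the hairpin and the line cannot be separated.

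Neighbouring genes were lower together along chromosome stretches in sh718 and sh720. A few strongly changed genes are argued against, since 86.3% of the held-out genes were below 0 (exact 95% interval 80.9% to 90.7%). That interval treats genes as independent. Neighbours measured in the same libraries against the same controls are not, so it is likely too narrow. A GC or length trend is argued against on chromosomes 3, 5, 10 and 11, where at least 80.6% of the median was kept without it, but cannot be told apart on chromosome 8, where 39.9% was kept. Different numbers of chromosome copies in the lines and regional regulation cannot be told apart and both stay open, since no DNA measurement was analysed here. The library medians (nearest to 0 in a hairpin library, -0.153) do not decide, since the stretches were chosen for being lower in the hairpin lines. For those found in sh720, which were lower in both lines against shared controls, it may be the control line that differs.

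For the numbers of called genes, the 6 libraries of a comparison allow only 10 splits, too few for a test. In sh718 against control, 1 split gave as many calls as the real one, which was the real one itself, with 1947 calls against at most 1 in any other. In sh720 against control it was again 1, with 655 against 0, and in sh718 against sh720 it was 1, with 2419 against 0.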

How the results depend on the processing

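Among the alternatives, the 1.5-fold minimum, 2 lines at a time, nuclear protein-coding genes alone, removal of the GC and length trend and genes outside the stretches were chosen after the data were seen. Direction was compared for the named genes and not for all tested genes. No named gene called in the main or the alternative fit reversed. Counts were compared by size alone, so they could not be scored as reversed. With the GC and length trend removed, the larger side of the calls did change in sh718 against control and against sh720, as given below. Of the called list medians, that of epithelial genes in sh718 turned from -0.05 to 0.0040 without sh718 library 3, 0.0067 without control library 1 and 0.0055 without control library 2, and was -0.22 without control library 3, the cause not tested. That of mitochondrial transcripts in sh718 turned from -0.16 to 0.065 with the GC and length trend removed. Among the named genes other than CTHRC1, 8035 values stayed on their side of the threshold, 197 lost a call and 32 gained one. Direction was compared only where a value was called in the main or the alternative fit. Among lists 1305 stayed, 22 lost a call, 13 gained one and 4 turned in sign. CTHRC1 stayed lower throughout, with leave-one-out log2 values of -6.11 to -5.65 in sh718 and -3.04 to -2.60 in sh720.

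Stricter rules shortened the counts. With DESeq2 as the test, 447 genes were higher and 561 lower in sh718, 132 and 166 in sh720, 34 and 63 in both, 40 in opposite directions, and 632 and 661 between the hairpins. All were edgeR calls too, and the cause was not tested. With a minimum of 1.5-fold, the same counts were 438, 671, 164, 156, 37, 54, 27, 630 and 811, smaller because genes with lesser changes drop out. By the rule of size they were 173, 326, 90, 82, 26, 20, 12, 247 and 396, where the libraries were summed, the test left out and a 2-fold limit set together, so the cause was not tested. With libraries summed and both hairpins as 1 arm, edgeR called 0 higher and 2 lower, and DESeq2 1 and 2. This changed 2 things at once, the number of libraries and the joining of lines that differ, and the cause was not tested. At an unadjusted p under 0.05 these fits had 106 and 47 genes.

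The correlation of the hairpin changes was 0.443 with no count minimum, 0.310 with a mean of at least 100 and 0.253 in nuclear protein-coding genes, the cause not tested. Leaving out 1 library at a time it ran from 0.264 to 0.344. In that setting, with fewer libraries, genes higher in sh720 numbered 218 (without control library 3) to 362, genes higher in both 52 (without sh720 library 2) to 83, and genes in opposite directions 54 (without control library 1) to 85. Other counts stayed within 1.5 times.

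The share of sh720 calls that were higher went from 50.1% to 62.2% with total counts alone, and that of sh718 against sh720 from 48.5% to 35.6%, the cause not tested. With the GC and length trend removed the latter was 57.5% (1384 higher and 1023 lower), and the share in sh718 against control went from 46.9% to 56.6%. With the replicate number as a block, the counts were 925 and 1052 in sh718 and 343 and 337 in sh720, and residuals showed no pairing by replicate number (r -0.0127 to 0.0219). With the GC and length trend removed, 1147 and 878 were called in sh718 and 324 and 352 in sh720. Outside the stretches, 69 were higher and 96 lower in both. Several list calls rest on the settings: the collagen call in sh718 had an adjusted p of 0.101 with a mean of at least 100, and 0.0743 with the GC and length trend removed, and the MAPK call 0.150 with no minimum. With that trend removed the G2/M list differed between the hairpins (0.19, adjusted p 0.0400). Other values for the rule of size were not run, since the replicated test took its place. At this depth, in simulated counts, most genes changed by 1.3-fold or 1.5-fold were missed. Fewer genes were changed there than were called in either hairpin line, which makes the adjusted threshold stricter than in the data.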

Other observations

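The genes named here were chosen after their values were seen, and no explanation was tested for them. Some genes outside the lists separated the lines. The translation elongation gene EEF1A1 went from 1068 ± 35.0 CPM in control to 410.4 ± 24.3 in sh718 (log2 -1.38, SE 0.07, adjusted p 4.29e-26) and 775 ± 30.9 in sh720 (log2 -0.46, SE 0.07, adjusted p 1.6e-07). The processed pseudogene AC107956.1, in the chromosome 11 stretch of sh718, changed by -0.80 in sh718 and -3.95 in sh720.

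Some widely expressed genes had few counts in the table. Over the 9 libraries, the aldolase gene ALDOA and the kinase gene ILK had 1 count each, TYMS 18, CDH1 15 and MCM2 21, and GAPDH had 868. All but GAPDH were too low for the test, and how reads were counted is not given in the sources used here.

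Replicate libraries differed by more than sampling noise alone, with a chi-square per degree of freedom of 1.39 to 2.86 between pairs of a line. In sh718, the pairs with library 2 gave 2.86 and 2.82, and libraries 1 and 3 gave 1.39. Mitochondrial ribosomal RNA held 5.18% of the counts of sh718 library 2, against 7.89% and 8.17% in sh718 libraries 1 and 3. Over all libraries it ran from 4.71% to 8.17%. Across genes, which are not independent replicates, the Spearman rho of log2 change with GC content was 0.124 in sh718 and -0.0592 in sh720.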
